A study of Mus musculus and Homo sapiens with 49 samples.

How the data were processed

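RNA and ribosome footprints were measured in kidneys of wild-type and Ppp1r15a uORF−/− mice, and RNA in HEK293 cells with changes of the PPP1R15A uORF. Of 49 samples, 33 have values in the 4 deposited tables, and 16 kidney samples, used by the submitters to tune the library preparation, have none and were left out. The deposited values are raw read counts per gene, per the file headers, which name featureCounts 2.0.0 as the counting tool. The submitters' processing notes name STAR for alignment, featureCounts for counting, and the builds mm10 for mouse and hg38 for human. The mouse tables hold 55228 genes for RNA and 55276 for footprints. The human tables hold 60588 rows each, made per the file headers with the GENCODE 33 annotation and 5 added sequences, 1 for each edited line. The release of the mouse annotation, the versions of STAR, the handling of reads that match several genes and any trimming are not given in the sources used here. Per the labels' protocols, RNA libraries came from captured mRNA and footprint libraries from fragments left by RNase I in the presence of cycloheximide. No genome sequence or read alignment was at hand, so reads within the uORF could not be told from reads of the main coding region, and a footprint count is over all exons of the gene.

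All numbers were computed from the counts as deposited with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Genes were kept by edgeR's expression filter with a minimum count of 10 and the groups of each fit, libraries were scaled by TMM, and each gene was tested with edgeR's quasi-likelihood F-test. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. The tests, the samples in each, the covariates, the alternatives, the gene lists and the rule for named genes were chosen before the data were examined, except where the text says otherwise.

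The LPS effect was fitted within each assay over 6 libraries with genotype as a term. The genotype difference after LPS and the difference of LPS responses were contrasts of 1 mean per genotype and treatment, in which the control groups of 1 library add no spread of their own. Translational efficiency was tested as the interaction of assay with treatment or genotype in 1 model over the 12 kidney libraries. The poly(I:C) effect was fitted over 18 HEK293 libraries with the pair of line and sequencing set as a block. The uORF−/− and 11mer lines were compared with the parental line at baseline over 12 libraries with the sequencing set as a term. The Streptag, NoPP_Streptag and 99mer lines have 1 library per treatment, so each was compared with the parental line over both treatments of the first set, and the spread came from the residuals of lines and treatments. The 3 libraries with the suffix _p were compared with the baseline libraries of the same lines.

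Each gene list was tested against all other genes by limma's camera with a preset correlation of 0.01 and again with a correlation estimated per list, and its direction by fry, all adjusted over the lists of a comparison. Counts of a list's genes are given over all genes tested and adjusted over the list alone. The targeted gene was named in every comparison. Further named genes were, among those past the threshold with a mean log2-CPM of at least 3 and the same direction in every replicate or pair, the 10 with the largest rise and the 10 with the largest fall, up to 4 members with the smallest p of each list described, and fixed marker genes. Of these the text names a part. Gene models without a known gene's symbol were left out of the ranked genes.

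CPM are counts divided by the total of a library, times 1e6, and the 95% intervals on single libraries are exact binomial intervals that cover counting error only. The total counts ran from 37.5e6 to 56.6e6 for kidney RNA, 13.1e6 to 44.9e6 for footprints, 6.49e6 to 27.6e6 for the first HEK293 set and 15.4e6 to 39.2e6 for the second. Kidney RNA and footprint libraries carry numbers in their titles that run from 1 to 6 in both assays, and the same number was taken as the same animal. As a check, deviations of RNA and of footprints from their group means were correlated across genes: 0.459 in uORF−/− LPS kidneys and 0.187 in wild type over 8619 genes with a mean log2-CPM over 3, and 0.247 and 0.0598 over the 20311 genes past the count filter. The fit with the animal as a block was an alternative.

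Each analysis was first tested on simulated counts with the real genes' means and library sizes and 200 genes changed 2-fold or 4-fold. edgeR found 55.8% of the 2-fold and 91.1% of the 4-fold changes for the LPS effect in kidney RNA, 58.8% and 79.6% for the genotype difference in RNA, 63.6% and 76.0% for that in footprints, 76.0% and 92.1% for poly(I:C), and 5.81% and 42.4% for the uORF−/− line at baseline. The alternatives were DESeq2's Wald test, RLE scaling, scaling without genes that take over 1% of a library, a minimum count of 30, no filter on low counts, genotype as an additive term, blocks or no blocks, each HEK293 set alone, and leaving out each library in turn. Fits without 2 baseline libraries of the first HEK293 set (11mer, which held transcripts of neutrophils and monocytes, and NoPP_Streptag, with high collagen transcripts), and fits with a share of the LPS footprints taken off the control footprint libraries, were added after the data had been seen.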

Results

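Kidneys of wild-type C57BL6 mice and of mice whose Ppp1r15a upstream open reading frame (uORF) had been removed (uORF−/−) were profiled by RNA sequencing and by sequencing of ribosome footprints. Lipopolysaccharide (LPS), a component of bacterial cell walls, was given at 5 mg/kg and kidneys were taken at 16 h, with kidneys of 0 h as controls. The labels do not say whether the 0 h kidneys had received an injection, so any effect of injection and of elapsed time is part of each LPS value. Each assay had 2 LPS libraries and 1 control library per genotype. The total counts of the libraries ran from 37.5e6 to 56.6e6 for RNA and from 13.1e6 to 44.9e6 for footprints. In HEK293 cells, a line of human embryonic kidney origin, RNA was sequenced at baseline and 16 h after transfection with poly(I:C), a double-stranded RNA mimic, at 1.0 µg/mL. The parental line was set beside lines with 5 changes of the PPP1R15A uORF, labelled uORF−/−, 11mer, 99mer, Streptag and NoPP_Streptag. The uORF−/− line is called noATG in some source names. By the source names each edited line is 1 clone. A difference that arose between clones can therefore not be told from an effect of the edit in any comparison of lines, and the p-values do not measure the spread between clones. The first sequencing set held all 6 lines with 12 libraries (6.49e6 to 27.6e6 counts), and the second held the parental, uORF−/− and 11mer lines with 9 libraries (15.4e6 to 39.2e6), 3 of which carry the suffix _p. A further 16 kidney samples have no deposited counts and were not analysed here. Changes are log2 fold changes ± standard error (SE), and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another tool is named. These p-values measure the spread between these samples.

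The first question was how removal of the uORF changed Ppp1r15a itself, the regulatory subunit that directs protein phosphatase 1 to eIF2α and so ends the integrated stress response. After LPS the footprints of Ppp1r15a were higher in uORF−/− kidneys than in wild type by 1.37 ± 0.13 (adjusted p = 0.017), at 79.4 ± 2.91 against 31.3 ± 4.35 CPM (counts per 1e6 counted; mean ± SD, n = 2 each). Its RNA was at 76.2 ± 10.5 against 72.7 ± 14.6 CPM, a difference of 0.11 ± 0.19 (adjusted p = 0.87) that did not exceed the spread between replicates. The ratio of footprint to RNA CPM was 1.05 ± 0.106 in uORF−/− LPS kidneys and 0.433 ± 0.0273 in wild-type LPS kidneys. In the single control kidneys, which have no replicate check, the ratio was 0.727 in uORF−/− and 0.444 in wild type. The uORF−/− control had 13.5 footprint CPM (95% exact binomial interval 11.6 to 15.7) and the wild-type control 4.68 (4.07 to 5.36). Control RNA was also higher in uORF−/−, at 18.6 CPM (17.5 to 19.8) against 10.5 (9.60 to 11.5) in wild type. The gene was counted over chromosome 7 from 45522916 to 45526268 of the mm10 build (ENSMUSG00000040435). As a difference of translational efficiency, the footprint change minus the RNA change, the genotype effect on Ppp1r15a was 1.26 ± 0.25 with all 4 LPS pairings higher. That value was short of the threshold when adjusted over all 20641 genes (unadjusted p = 0.000236, adjusted p = 1.00). With the animal as a block it was 1.25 ± 0.17 (adjusted p = 6.65e-10), and without a filter on low counts 1.24 ± 0.19 (adjusted p = 1.22e-06). In both of these fits the spread was pooled over genes, so these p-values do not measure the spread of Ppp1r15a alone. DESeq2 gave an adjusted p of 0.097. Without uORF−/− LPS RNA library 1 the RNA difference of Ppp1r15a was −0.04, and without wild-type LPS RNA libraries 1 and 2 it was 0.43 ± 0.18 (unadjusted p = 0.030, adjusted p = 0.31) and −0.17.

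**Figure D1:**
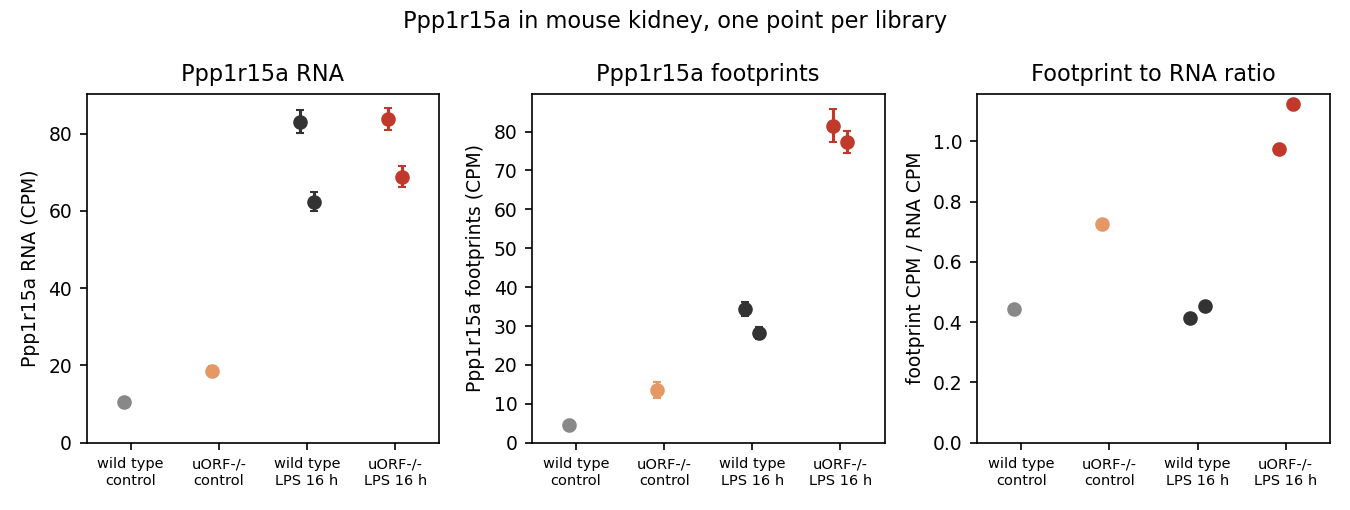
Ppp1r15a in each kidney library, as RNA CPM, footprint CPM and the ratio of footprint to RNA CPM, for wild-type and uORF−/− kidneys at 0 h and 16 h after LPS. Points are libraries (1 per control group, 2 per LPS group) with 95% counting intervals on the CPM, and the ratio was 0.974 and 1.12 in the uORF−/− LPS kidneys against 0.414 and 0.453 in the wild-type LPS kidneys.

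Apart from Ppp1r15a, few genes differed between the genotypes after LPS. In RNA, 8 of 17918 genes differed, 7 higher and 1 lower in uORF−/− kidneys. Those higher were led by Hba-a2, an alpha-globin (1.46 ± 0.16, adjusted p = 0.0040), Ucp1, the uncoupling protein of brown fat (1.33 ± 0.19, 0.036), Cyp2a5 (1.27 ± 0.19, 0.039) and Cyp4a12a (1.21 ± 0.16, 0.026), both cytochrome P450 enzymes, and Clec2h, a C-type lectin (1.14 ± 0.16, 0.035). The other 3 lay below the expression floor of the rule for named genes and were chosen after their values were seen: Igkc, an immunoglobulin light chain (3.08 ± 0.26, 0.00076), and Synpr (3.58 ± 0.36, 0.0029) were higher, and Cnbd2 (−2.06 ± 0.27, 0.026) was lower. In footprints, 10 of 19193 genes were higher and 0 lower. Beside Ppp1r15a they held Plin1, the coat protein of fat droplets (1.76 ± 0.16, 0.017), Ucp1 (1.65 ± 0.20, 0.048), Car3, a carbonic anhydrase abundant in fat and muscle (1.15 ± 0.12, 0.020), the macrophage mannose receptor gene Mrc1 (1.13 ± 0.12, 0.020), Cyp2a5 (1.21 ± 0.12, 0.020), Hrg, which encodes histidine-rich glycoprotein (1.20 ± 0.14, 0.033), and the immunoglobulin genes Igha (3.60 ± 0.35, 0.017) and Igkc (2.97 ± 0.29, 0.017), with Jchain (3.12 ± 0.38, 0.045) again chosen after its value was seen. Each of these was higher in all 4 pairings of an uORF−/− with a wild-type LPS library, which the rule for named genes already required of the ranked ones. The list of 12 adipocyte genes had 1 member higher in RNA and 2 in footprints, and adjusted over the list alone 3 higher in RNA, and 8 higher and 1 lower in footprints. That list was above the other genes in both assays, but not with an estimated correlation (adjusted p = 0.544 for RNA and 0.574 for footprints). Hba-a2, Cyp2a5 and Cyp4a12a share reads with near-identical copies, and the immunoglobulin genes with related segments, so their own shares are uncertain. On simulated data of the same depth the footprint comparison made 200 calls, of which 42 were false, so some of the 10 footprint genes may be false calls. The counts depended on single libraries. Leaving out 1 LPS library at a time gave 182 and 77 RNA genes without uORF−/− libraries 1 and 2, and 59 and 49 without wild-type libraries 1 and 2. For footprints it gave 126 genes without uORF−/− library 1, and 20 and 32 without wild-type libraries 1 and 2. By DESeq2 the counts were 93 in RNA and 76 in footprints, and with treatment and genotype as additive terms 1 in each. In that fit, which includes the controls, Ppp1r15a kept its footprint call (1.43) and Synpr its RNA call (3.18), and all other named calls ended. Plin1 was at 0.73, Ucp1 at 0.73, Car3 at 0.47 and Mrc1 at 0.48 in footprints, and Hba-a2 was at 0.86 and Clec2h at 0.50 in RNA. The immunoglobulin calls ended narrowly with folds that stayed large. Igha was at 3.24, Igkc at 2.62 and Jchain at 2.87 in footprints (adjusted p = 0.058 each), and Igkc at 2.545 in RNA (0.060). Single calls ended for Ucp1 and Cyp2a5 in RNA (without wild-type LPS library 1, adjusted p = 0.053, and without the uORF−/− control, 0.0527). In footprints they ended for Mrc1, Hrg and Ucp1 without uORF−/− LPS library 2 (adjusted p = 0.0578, 0.0679 and 0.0892), for Hrg also without wild-type LPS library 2 (0.0562), for Ucp1 also without the wild-type control (0.0647), and for Jchain without wild-type LPS library 1 (0.0513). With RLE scaling the calls of Cyp2a5 in RNA and Ucp1 in footprints ended (0.054 each), and with a minimum count of 30 those of Cyp2a5 in RNA (0.0554) and of Ucp1 and Jchain in footprints (0.0827 each).

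**Figure D2:**
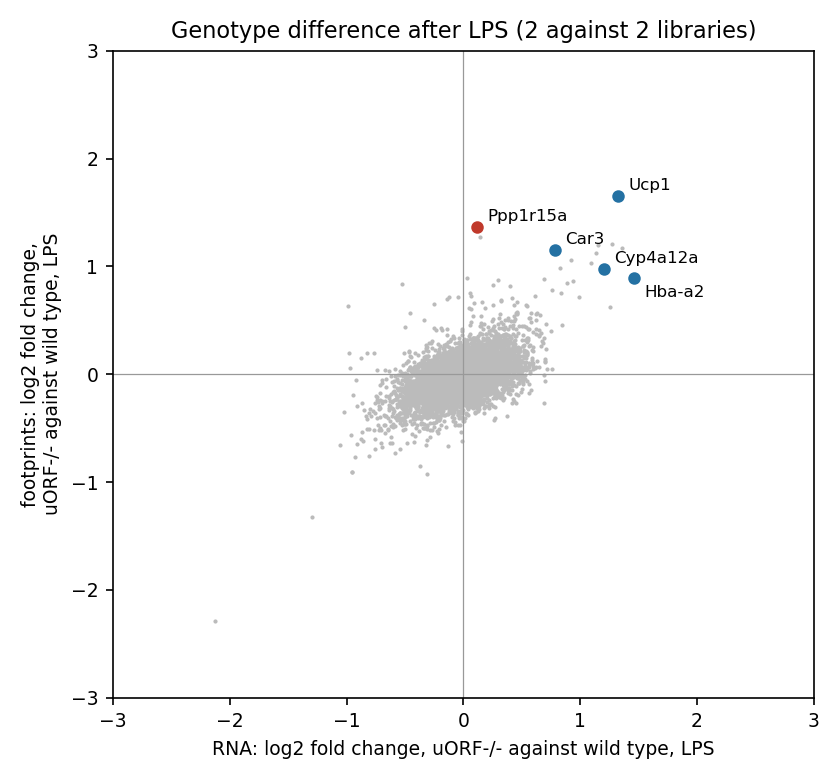
Difference between uORF−/− and wild-type kidneys after LPS (2 against 2 libraries) as log2 fold change of RNA on the horizontal axis and of footprints on the vertical axis. Each grey point is 1 gene with a mean log2-CPM of at least 3 in both assays, and Ppp1r15a lies near 0 for RNA (0.11) and at 1.37 for footprints, whereas Ucp1 passed the test in both assays, Car3 in footprints alone, and Cyp4a12a and Hba-a2 in RNA alone.

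For translational efficiency 0 of 20641 genes differed between the genotypes by edgeR and 0 by DESeq2, with 768 genes at an unadjusted p under 0.05. With the animal as a block 52 genes differed, 34 higher and 18 lower, and Ppp1r15a was among those higher. The smallest p was that of the row CT010467.1, also higher, and mt-Te and mt-Tq were among those lower. The spread of this block fit was pooled over genes, so the 52 calls do not measure the spread of each gene alone. Their cause was not tested. In the same block fit 5 of 20 acute phase and complement genes, which encode plasma proteins made largely in liver, were higher and 0 lower (list adjusted p = 0.000470 with the preset correlation and 0.697 with an estimated one). In tests on simulated data of the same depth, this comparison found 27.8% of genes changed 2-fold and 51.0% of those changed 4-fold. Leaving out wild-type LPS RNA library 1 gave 2 genes.

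The LPS response of uORF−/− kidneys was then set against that of wild type as an interaction, in which each control is 1 library assumed to vary like the LPS groups. In RNA 14 genes differed, 7 each way. The response was more negative in uORF−/− kidneys for Slc14a2, the urea transporter of the inner medulla (−4.22 ± 0.39, adjusted p = 0.0025), Cish, a suppressor of cytokine signalling (−2.81 ± 0.29, 0.0040), Slco4a1, an organic anion transporter (−2.49 ± 0.35, 0.023), and Umod, which encodes the uromodulin of the thick ascending limb (−1.84 ± 0.24, 0.014). It was more positive for Bcl6, a transcriptional repressor (2.14 ± 0.26, 0.012), Fabp4, the fatty acid carrier of adipocytes (1.94 ± 0.28, 0.026), Clec2h (1.82 ± 0.27, 0.028), and Gadd45a, a growth arrest gene (1.73 ± 0.27, 0.036). In footprints 33 genes differed, 23 more positive and 10 more negative, and with RLE scaling the split was 19 and 15. Slc14a2 (−4.07 ± 0.40, 0.015) and Aqp2, the water channel of the collecting duct (−2.38 ± 0.20, 0.015), were more negative, and Plin1 (2.84 ± 0.26, 0.015), Ucp1 (2.90 ± 0.35, 0.030), Car3 (2.18 ± 0.21, 0.015) and Mrc1 (2.02 ± 0.21, 0.017) more positive. The interaction for Ppp1r15a itself was −0.65 ± 0.33 in RNA (adjusted p = 0.69) and −0.18 ± 0.25 in footprints (0.81), neither past the threshold. DESeq2 gave 45 RNA genes and 202 footprint genes. Without uORF−/− LPS libraries 1 and 2 the RNA count was 146 and 80, and without wild-type LPS libraries 1 and 2 it was 49 and 62. The footprint count was 178 without uORF−/− LPS library 1, and 61 and 156 without wild-type LPS libraries 1 and 2.

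Most genes of the kidney differed between 16 h after LPS and 0 h. Of 16836 genes, 4951 rose and 5100 fell in RNA, with genotype as a term. Ppp1r15a rose by 2.80 ± 0.22 (adjusted p = 1.9e-06) and Atf4, the transcription factor of the integrated stress response, by 2.19 ± 0.13, each in 4 of 4 LPS libraries against the control of the same genotype. Large rises that rested on more than a few control counts included those of Cxcl10, the interferon-induced chemokine (10.00 ± 0.22), and Lcn2, the tubule injury marker NGAL (9.68 ± 0.45). All 30 interferon-stimulated genes rose, such as Mx1 (7.75 ± 0.20), Ifit1 (7.49 ± 0.21) and Usp18 (5.69 ± 0.17), with the same count adjusted over the list alone. All 28 inflammatory cytokine and chemokine genes rose, among them Il1rn, the interleukin 1 receptor antagonist (7.84 ± 0.23), and Nfkbia, an inhibitor of NF-κB (3.77 ± 0.14). Of 20 acute phase genes 18 rose (19 adjusted over the list alone), such as the fibrinogen gene Fgg (9.65 ± 0.25). Of 20 tubule injury genes 19 rose, including Sox9 (8.91 ± 0.28) and Havcr1, the gene of KIM-1 (6.10 ± 0.23). All 14 immediate early genes rose, such as Klf6 (5.63 ± 0.21), and all 15 neutrophil genes, such as S100a9 (6.88 ± 0.24) and S100a8 (6.76 ± 0.29). Of 29 integrated stress response genes 22 rose and 3 fell; Atf3 rose by 6.16 ± 0.20, while Ddit3, which encodes CHOP, rose by only 0.47 ± 0.19 (adjusted p = 0.046). Among 14 NRF2 target genes 10 rose, led by the haem oxygenase gene Hmox1 (3.90 ± 0.19).

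In several other gene lists more genes fell than rose. Of 20 cholesterol synthesis genes 14 fell and 2 rose, with Stard4, a cholesterol carrier, at −2.27 ± 0.15 and the synthase gene Hmgcs1 at −1.73 ± 0.12. Of 25 genes of the loop of Henle, distal tubule and collecting duct 15 fell and 3 rose, with the chloride channel subunit gene Bsnd (−4.53 ± 0.32), the potassium channel gene Kcnj1 (−3.83 ± 0.20) and the anion exchanger gene Slc4a1 (−3.12 ± 0.16) among those that fell. Of 29 proximal tubule genes 13 fell and 5 rose. Gatm, which makes the creatine precursor, was at −2.97 ± 0.19, Lrp2, which encodes megalin, at −1.18 ± 0.12, and the phosphate transporter gene Slc34a1 at −0.50 ± 0.14 (adjusted p = 0.0099). Of 14 fibroblast and pericyte genes 9 fell and 1 rose, with Col1a1 at −2.23 ± 0.20. Igfbp5 (−3.94 ± 0.12), the endothelial receptor gene Tek (−3.74 ± 0.16) and Veph1 (−4.11 ± 0.16) were among the largest falls, and Ppargc1a, a regulator of mitochondrial genes, fell by 2.24 ± 0.12. Among 20 macrophage and monocyte genes 9 rose, such as the LPS coreceptor gene Cd14 (7.40 ± 0.27), and 10 fell, such as the chemokine receptor gene Cx3cr1 (−6.76 ± 0.35). In the test of each list against the other genes with an estimated correlation, the interferon-stimulated list was past the threshold (adjusted p = 0.0492). The others passed with the preset correlation alone; with an estimated one their adjusted p was 0.100 for cytokines and for acute phase genes, 0.109 for injury, 0.112 for neutrophil and cholesterol genes and 0.141 for immediate early, stress response and fibroblast genes. It was 0.236 for NRF2 targets, 0.426 for loop and distal tubule genes and 0.700 for proximal tubule genes. The calls of Ddit3 and Slc34a1 ended without single libraries, Ddit3 in 5 of 6 cases (adjusted p up to 0.186, without the wild-type control) and with no filter on low counts (0.102), and Slc34a1 without the uORF−/− control (0.0832) or uORF−/− LPS library 2 (0.0509).

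**Figure D3:**
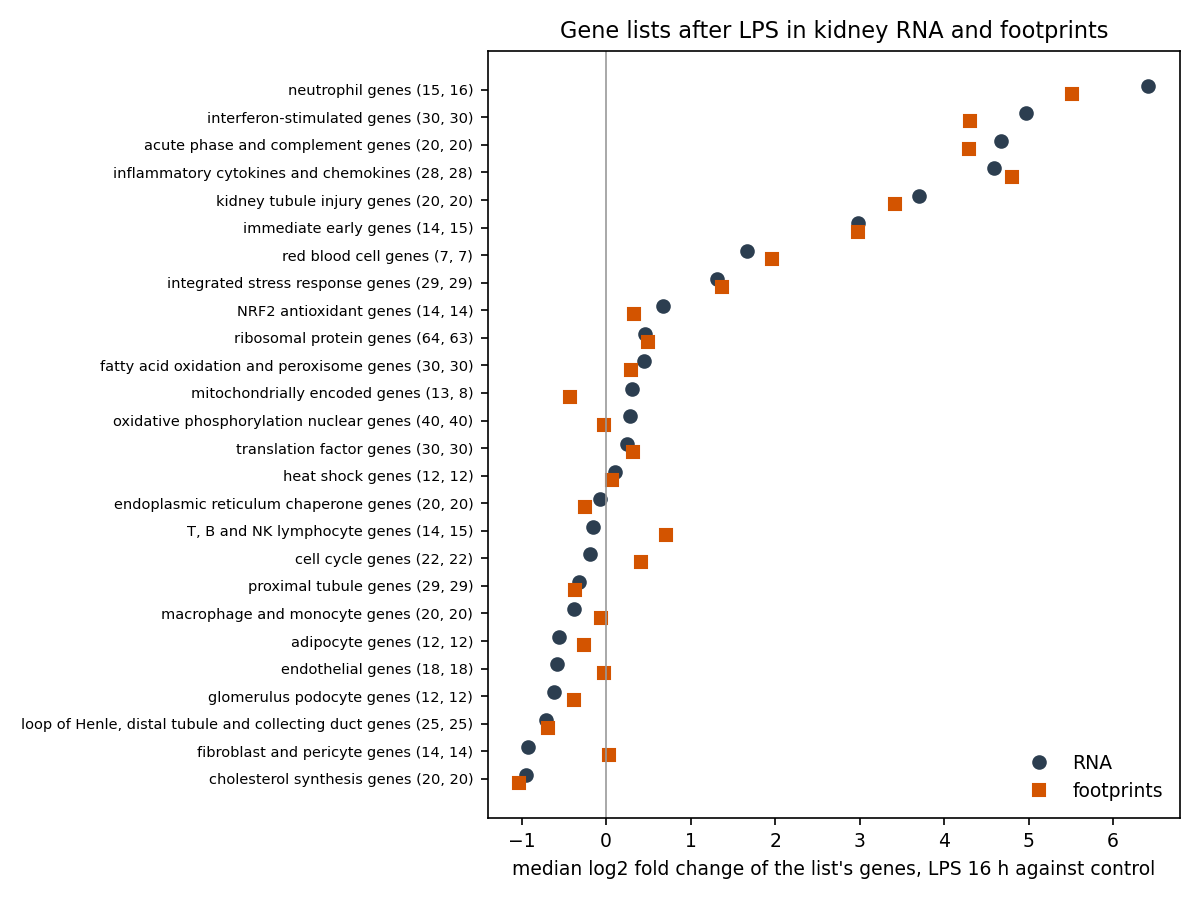
Median log2 fold change of the genes of each list, LPS 16 h against 0 h control, in kidney RNA (circles) and footprints (squares), with the number of genes tested in RNA and in footprints in brackets. Interferon-stimulated genes had medians of 4.97 in RNA and 4.31 in footprints, and cholesterol synthesis genes −0.95 and −1.03.

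Footprints followed the same comparison with 5042 of 17722 genes rising and 5117 falling. Ppp1r15a footprints rose by 2.89 ± 0.14 (adjusted p = 5.9e-07) and those of Atf4 by 2.10 ± 0.13. Lcn2 (6.75 ± 0.39), Fgg (6.75 ± 0.38), Serpina3f, a serine protease inhibitor (6.67 ± 0.22), and Cxcl10 (6.64 ± 0.31) were among the largest rises. For genes almost silent in control RNA the control footprint libraries held 0.769% (uORF−/−) and 0.902% (wild type) of the mean raw LPS footprint count. These shares were not scaled for depth. Such reads limit how large a footprint rise of such genes can be. In RNA Lcn2 rose by 9.68 and Cxcl10 by 10.00. All 30 interferon-stimulated genes rose, such as Ifit1 (5.97 ± 0.14; list adjusted p = 0.0476 with an estimated correlation), and 27 of 28 cytokine genes, such as Ccl5 (6.09 ± 0.16; 0.0913). Of 20 injury genes 19 rose, with Timp1, an inhibitor of matrix proteases, at 6.02 ± 0.15 and Havcr1 at 5.84 ± 0.25 (0.0913 for the list). All 20 acute phase genes rose (0.235), and the small heat shock gene Hspb1 rose by 2.69 ± 0.14. Of 20 cholesterol synthesis genes 14 fell and 0 rose, such as Dhcr7 (−2.26 ± 0.12) and Hmgcs1 (−1.95 ± 0.13; 0.0913). Of 25 loop and distal tubule genes 15 fell and 2 rose, with Kcnj1 at −3.50 ± 0.19 and the water channel gene Aqp3 at −2.33 ± 0.10 (0.325), and of 29 proximal tubule genes 15 fell and 2 rose, with Gatm at −3.93 ± 0.18, Lrp2 at −0.78 ± 0.13 and Slc34a1 at −0.61 ± 0.13 (0.738). Pcdh12, an endothelial cadherin (−4.08 ± 0.14), Veph1 (−3.92 ± 0.15) and the natriuretic peptide receptor gene Npr3 (−3.53 ± 0.21) also fell. Across 15513 genes measured in both assays the changes of RNA and footprints had a Pearson r of 0.901 and a Spearman rho of 0.872; genes are not independent replicates. Of 7538 genes called in both, 7456 moved the same way and 82 opposite ways.

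Translational efficiency under LPS, the change in footprints beyond that in RNA, rose for 442 and fell for 316 of 19106 genes. For Ppp1r15a it was 0.10 ± 0.27 (adjusted p = 0.90). It was −0.24 without the uORF−/− control RNA library, −0.01 without uORF−/− LPS RNA library 2 and −0.02 without the wild-type control footprint library. This model takes 1 LPS effect for both genotypes, so a difference between their responses is part of its spread. The ratio of footprint to RNA CPM was 0.727 in the single uORF−/− control and 1.05 after LPS. In wild type it was 0.444 in the single control and 0.433 after LPS. The interferon-stimulated genes fell as a group, 17 of 30 falling and 0 rising (18 falling and 1 rising adjusted over the list alone; adjusted p = 0.00953 with an estimated correlation). With the animal as a block 19 fell, and the list did not pass with an estimated correlation (adjusted p = 0.377). Gbp2, a guanylate-binding protein (−2.48 ± 0.30), Ifit2 (−2.35 ± 0.28), Ifit1 (−1.50 ± 0.18) and the ubiquitin-like gene Isg15 (−1.16 ± 0.18) were among them. Cxcl10 (−3.35 ± 0.30), Slfn4 (−4.29 ± 0.53), Lcn2 (−2.92 ± 0.52), the fibrinogen gene Fgb (−3.03 ± 0.66) and Cxcl1, a neutrophil chemokine (−3.41 ± 0.76), fell as well. The control footprint libraries held reads of genes almost silent in control RNA, at 0.769% (uORF−/−) and 0.902% (wild type) of their LPS footprint level. With that share taken off the controls, 2 of the 30 interferon-stimulated genes fell, their median went from −0.86 to −0.24 and the list did not pass with the preset correlation (adjusted p = 0.165). Efficiency values became 0.26 for Cxcl10, 0.05 for Ifit1, −0.31 for Ifit2, 0.61 for Gbp2, −0.53 for Isg15, 0.28 for Fgb and −1.12 for Cxcl1, none past the threshold. These values depended on single control libraries. With the share taken off and the uORF−/− control footprint library left out, Ifit1 was at −0.70, Ifit2 at −1.01, Gbp2 at −0.67 and Isg15 at −0.87. With the wild-type control footprint library left out instead, they were at 1.76, 0.93, 11.9 and −0.005. With the share taken off and all libraries kept, Slfn4 still fell (−2.94 ± 0.56, adjusted p = 0.014), and Lcn2 had 9.60 against controls left near 0 counts. Among those that rose were the matrix genes Vcan (2.51 ± 0.41) and Tnc (2.34 ± 0.28), the vasopressin receptor gene Avpr1a (2.08 ± 0.21), Aldh1a3, a retinoic acid enzyme (2.03 ± 0.23), Vim, which encodes vimentin (1.48 ± 0.20), and the kinase gene Wnk1 (1.16 ± 0.15). Of 14 fibroblast and pericyte genes 6 rose and 0 fell (9 adjusted over the list alone; adjusted p = 0.166 with an estimated correlation), with Pdgfra at 1.38 ± 0.19, Acta2 at 1.10 ± 0.19 and the renin gene Ren1 at 0.92 ± 0.17. Of 20 acute phase genes 8 fell and 1 rose (0.203), and of 40 nuclear genes of oxidative phosphorylation 4 fell and 0 rose (9 adjusted over the list alone; 0.414). With the animal as a block 2328 genes differed, 1253 rising and 1075 falling, and DESeq2 gave 1525. Leaving out 1 library at a time gave from 129 genes (without the uORF−/− control RNA library) to 1122 (without wild-type LPS RNA library 2). Without either uORF−/− control library the calls of Fgb, Cxcl1 and Acta2 ended (adjusted p from 0.0671 to 0.141), as did that of Cxcl1 without the wild-type control RNA library (0.0508). The call of Ren1 ended without any control library but the wild-type RNA one (adjusted p from 0.0621 to 0.112), and Vcan was at 1.36 (0.0709) without the uORF−/− control RNA library.

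In HEK293 cells, poly(I:C) was compared with baseline over 9 pairs of libraries of the same line and set. PPP1R15A RNA rose by 1.27 ± 0.19 (adjusted p = 0.00084), higher in 9 of 9 pairs, by 1.15-fold to 3.08-fold in the first sequencing set and by 3.99-fold to 4.50-fold in the second. The change was 0.86 in the first set alone and 2.0 in the second alone. Of 17357 genes, 120 rose and 68 fell. Interferon-stimulated genes led the rise: 29 of 33 rose and 0 fell (31 adjusted over the list alone; adjusted p = 0.000313 with an estimated correlation). Examples were IFIT2 (7.64 ± 0.93), IFIT3 (7.47 ± 0.66), OASL (6.45 ± 0.53), IFIT1 (6.42 ± 0.34), OAS2 (6.29 ± 0.80), IFI44 (6.14 ± 0.80), OAS1 (6.02 ± 0.72), IFI44L (5.99 ± 0.39), IFI6 (4.15 ± 0.16) and IFIT5 (3.30 ± 0.16). The interferon gene IFNB1 had 1 count in all 9 baseline libraries together and from 65 to 1592 counts in each poly(I:C) library. Of 18 cytokine genes 5 rose and 0 fell (10 adjusted over the list alone; 0.174), among them the chemokine genes CXCL10 (8.14 ± 0.50) and CCL5 (7.65 ± 0.54), the transcription factor gene IRF1 (1.55 ± 0.23) and the growth factor gene CSF1 (1.46 ± 0.18). The apoptosis gene PMAIP1 and the initiation factor gene EIF5 rose by 0.53 ± 0.11 and 0.39 ± 0.09. ATF4 (0.25 ± 0.14, 0.47) and DDIT3 (0.68 ± 0.40, 0.51) did not pass the test, and DDIT3 was at −0.18 in the first set alone. The falls were smaller, such as HSPG2, which encodes perlecan (−0.72 ± 0.12), UTRN, which encodes utrophin (−0.72 ± 0.13), the scaffold gene AHNAK (−0.60 ± 0.10), the guidance gene SLIT3 (−0.88 ± 0.18) and the collagen gene COL6A1 (−0.45 ± 0.09). By DESeq2 220 genes rose and 261 fell, the first set alone gave 78 genes and the second alone 295. Leaving out 1 library gave from 97 genes (parental poly(I:C) library of the second set) to 638 (11mer baseline library of the first set), and 626 without the 11mer poly(I:C) library of the first set. The calls of SLIT3 and COL6A1 ended for 8 of 18 libraries each (adjusted p up to 0.0763 and 0.0856), that of PMAIP1 for 8 (0.0712) and that of EIF5 for 11 (0.138). These 4 calls also ended in the first set alone (0.320, 0.243, 0.223 and 0.282), as did those of IRF1 (0.0762), HSPG2 and UTRN (0.135 each). In the second set alone those of HSPG2 (0.0667), UTRN (0.0855), AHNAK (0.140), PMAIP1 (0.0781) and EIF5 (0.0937) ended, and without the block of pairs those of HSPG2 (0.145), AHNAK (0.100), SLIT3 (0.0564), PMAIP1 (0.108) and EIF5 (0.178). With no filter on low counts those of COL6A1 (0.235) and EIF5 (0.286) ended.

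**Figure D4:**
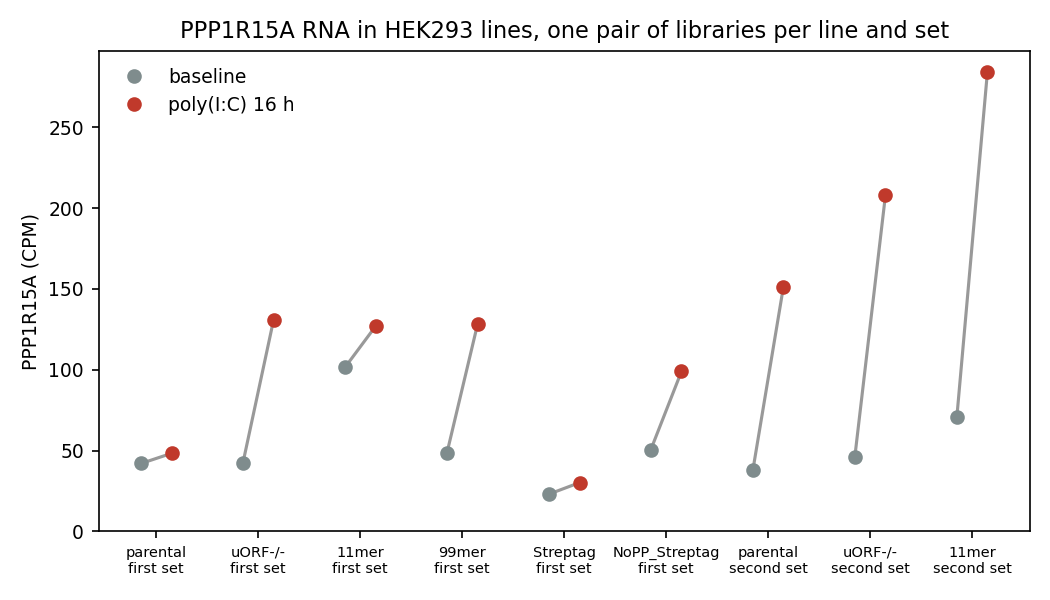
PPP1R15A RNA in CPM in each HEK293 line and sequencing set, with a line joining the baseline and the poly(I:C) library of a pair. The poly(I:C) library was the higher in 9 of 9 pairs, by 1.15-fold (parental, first set) to 4.50-fold (uORF−/−, second set).

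The uORF−/− and 11mer lines were compared with the parental line at baseline, with 1 library per line in each set and the set as a term. Both comparisons used the same parental baseline libraries, so a likeness between the 2 lines is not independent evidence. PPP1R15A RNA was not past the threshold in either line, at 0.25 ± 0.34 (adjusted p = 0.94) in uORF−/− and 0.85 ± 0.35 (0.79) in 11mer. For uORF−/− the value was −0.05 without its own baseline library of the first set and −0.10 without the parental baseline library of the second. In the uORF−/− line 137 of 27093 genes were higher and 118 lower. The cancer-testis antigen genes MAGEB2 (4.58 ± 0.38), MAGEA6 (4.35 ± 0.34) and MAGEA3 (3.27 ± 0.37), AFF2 (6.31 ± 0.67), APC2 (3.31 ± 0.39), the collagen gene COL3A1 (3.34 ± 0.49), the matrix protein gene SPARC (3.07 ± 0.32) and the transcription factor gene HAND1 (2.66 ± 0.28) were higher. DTX3, a ubiquitin ligase gene (−7.75 ± 0.58), the zinc finger gene ZNF426 (−4.74 ± 0.57), TMEM178B (−3.33 ± 0.32), TSC22D3, a glucocorticoid-induced gene (−2.80 ± 0.34), the mitochondrial reductase gene DECR1 (−2.53 ± 0.33), the enolase gene ENO2 (−2.21 ± 0.29) and the apolipoprotein gene APOE (−2.09 ± 0.39) were lower. Of 30 integrated stress response genes 2 were lower, ATF3 (−2.17 ± 0.51) and DDIT4 (−1.94 ± 0.38), and 7 adjusted over the list alone (adjusted p = 0.736 with an estimated correlation). ATF4 (−0.57 ± 0.37), ASNS, the asparagine synthetase gene (−1.36 ± 0.48), and DDIT3 (−1.18 ± 0.55) did not pass the test, and DDIT3 was at 0.03 without the parental baseline library of the first set. Of 14 hypoxia and glycolysis genes 2 were lower, the growth factor gene VEGFA (−1.35 ± 0.26) and the glucose transporter gene SLC2A1 (−1.07 ± 0.26), and 4 adjusted over the list alone (0.736). In the 11mer line 5 genes were higher and 0 lower: MAGEB2 (4.46 ± 0.38), MAGEA6 (3.59 ± 0.33) and MAGEA3 (2.74 ± 0.37), and NLRP1 (4.28 ± 0.74) and GABRA3 (3.24 ± 0.57), both chosen after their values were seen. MAGEA3 and MAGEA6 are near-identical, so the split of reads between them is uncertain. The 11mer baseline library of the first set held transcripts of neutrophils and monocytes, such as IL1B at 152 CPM. By DESeq2 487 genes differed in uORF−/− and 12 in 11mer, and without the set as a term 5 and 0. Leaving out 1 library gave from 96 genes (without the uORF−/− baseline library of the second set) to 755 (without the 11mer baseline library of the second set) for uORF−/−, and from 8 to 998 (11mer baseline libraries of the first and the second set) for 11mer. The calls of NLRP1 and GABRA3 ended without the parental baseline library of the second set (adjusted p = 0.0789 and 0.0654), and that of NLRP1 without the 11mer baseline library of the first (1.00). Without the uORF−/− baseline library of the second set the calls of APOE, ATF3, DDIT4, VEGFA and SLC2A1 ended (adjusted p = 0.292, 0.0774, 0.0785, 0.454 and 0.409), and without the parental baseline library of the first set those of ATF3, DDIT4, VEGFA and SLC2A1 (0.149, 0.168, 0.174 and 0.0955). Without the 11mer poly(I:C) library of the first set the calls of VEGFA (0.0539) and SLC2A1 (0.289) ended, and SLC2A1 lost its call without the uORF−/− baseline library of the first set (0.452) and the parental one of the second (0.514), 5 of 12 libraries in all. ATF3 did not pass by DESeq2 (0.19) or with a minimum count of 30 (0.115), nor SLC2A1 with no filter (0.35).

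The poly(I:C) responses of these lines did not differ from that of the parental line for any of 27093 genes by edgeR or DESeq2 (0 genes each), with 491 genes at an unadjusted p under 0.05 for uORF−/− and 635 for 11mer. For PPP1R15A the difference of responses was 0.64 ± 0.49 in uORF−/− and 0.12 ± 0.49 in 11mer (adjusted p = 1.00 each). The 11mer value was −0.30 and −0.35 without the parental baseline and poly(I:C) libraries of the first set, and −0.19 and −0.49 without the 11mer baseline and poly(I:C) libraries of the second. In tests on simulated data these comparisons found 38.8% and 34.9% of genes changed 4-fold. Leaving out 1 library gave up to 202 genes (without the uORF−/− poly(I:C) library of the first set) and 213 genes (without the 11mer baseline library of the second).

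The Streptag, NoPP_Streptag and 99mer lines were each compared with the parental line over both treatments within the first set. All 3 comparisons used the same 2 parental libraries, so a likeness between the lines is not independent evidence. Of 30 genes of the integrated stress response 21 fell in Streptag, 23 in NoPP_Streptag and 21 in 99mer with 0 rising in each, and adjusted over the list alone 25, 25 and 24 fell, with 1 rising in 99mer. With an estimated correlation the adjusted p was 0.133, 0.0670 and 0.0903. DDIT4, an inhibitor of mTOR signalling, was lower in all of them (−4.35 ± 0.24 in Streptag, −3.69 ± 0.23 in NoPP_Streptag and −3.21 ± 0.23 in 99mer). So was DDIT3 (−1.92 ± 0.47, −1.49 ± 0.47 and −2.0 ± 0.47), ASNS (−1.90 ± 0.59, −2.74 ± 0.62 and −2.12 ± 0.60) and TSC22D3 (−3.36 ± 0.19, −2.62 ± 0.18 and −3.26 ± 0.19). ATF4 was at −0.52 ± 0.17 in Streptag (adjusted p = 0.063), −1.33 ± 0.18 in NoPP_Streptag and −1.0 ± 0.17 in 99mer. The tRNA synthetase gene AARS1 (−1.09 ± 0.18) and the glutathione-degrading enzyme gene CHAC1 (−2.36 ± 0.34) fell in Streptag, the serine hydroxymethyltransferase gene SHMT2 (−1.81 ± 0.18) in NoPP_Streptag, and STC2 (−2.01 ± 0.22), CTH, a cysteine synthesis gene (−2.02 ± 0.28), and the cystine transporter gene SLC7A11 (−2.04 ± 0.37) in 99mer. PPP1R15A itself was at −0.85 ± 0.26 in Streptag (adjusted p = 0.038), 0.26 ± 0.25 in NoPP_Streptag (0.62) and 0.76 ± 0.25 in 99mer (0.071). The Streptag call ended without the parental baseline library (−0.26) and without the Streptag poly(I:C) library (−0.53), and with a minimum count of 30 (adjusted p = 0.0657). ASNS lost its call for 8 of 12 libraries in Streptag (adjusted p up to 0.469), 2 in NoPP_Streptag (0.159) and 6 in 99mer (0.518), and with no filter on low counts in Streptag (0.137) and 99mer (0.0949). DDIT3 lost it without the parental or the line's own poly(I:C) library in NoPP_Streptag (0.262 and 0.273), by DESeq2 there (0.150) and with a minimum count of 30 (0.118), and DDIT3 and ATF4 without the parental poly(I:C) library (0.0508 and 0.0832) or the line's own baseline library (0.215 and 0.148) in 99mer.

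Other groups of genes moved in these lines too. Of 64 ribosomal protein genes 60 fell in NoPP_Streptag (64 adjusted over the list alone; adjusted p = 0.0670 with an estimated correlation), 30 in Streptag (36; 0.362) and 15 in 99mer (24; 0.527), with RPL13A at −2.13 ± 0.17 in NoPP_Streptag and −1.25 ± 0.17 in Streptag. Of 40 nuclear genes of oxidative phosphorylation 31 fell in NoPP_Streptag (0.0670), such as COX5A (−1.49 ± 0.18), and 9 in Streptag (0.362). The elongation factor gene EEF1A1 fell in NoPP_Streptag (−1.44 ± 0.15) and in 99mer (−1.20 ± 0.15). Mitochondrially encoded genes rose, 10 of 13 in Streptag, 7 in NoPP_Streptag and 10 in 99mer (adjusted p = 0.362, 0.349 and 0.503 with an estimated correlation), for example MT-ND2 by 1.66 ± 0.21 in Streptag and by 1.52 ± 0.21 in NoPP_Streptag. Of 15 hypoxia and glycolysis genes 8, 10 and 7 fell (0.361, 0.153 and 0.503), such as PGK1 in Streptag (−1.85 ± 0.20) and LDHA in NoPP_Streptag (−1.37 ± 0.16), both glycolytic enzymes. MAGEA6 was higher in Streptag (3.91 ± 0.29), NoPP_Streptag (3.14 ± 0.28) and 99mer (3.69 ± 0.29). No test compared the edited lines with each other. Against the parental line IGFBPL1 (4.41 ± 0.28) and the transcription factor genes MSX2 (3.22 ± 0.21) and HAND1 (3.0 ± 0.19) rose in Streptag, where the cathepsin gene CTSF (−8.10 ± 0.43) and the filament gene INA (−6.63 ± 0.42) fell. MSX2 and HAND1 also rose in NoPP_Streptag and 99mer. The chemokine gene CXCL12 (2.70 ± 0.31) rose in NoPP_Streptag, where NELL2 (−4.42 ± 0.34) fell. The metallothionein gene MT1F (3.34 ± 0.37), the sphingosine kinase gene SPHK1 (2.67 ± 0.23) and OAS3 (2.46 ± 0.35) rose in 99mer, where MGST1, a glutathione transferase gene (−4.62 ± 0.41), fell. Of 27277 genes, 999 rose and 1061 fell in Streptag, 700 and 1784 in NoPP_Streptag, and 852 and 877 in 99mer. With RLE scaling the 99mer split was 1284 and 845. The median of all genes went from 0.139 with TMM to 0.184 with RLE in NoPP_Streptag and from 0.028 to 0.102 in 99mer. In the baseline comparison of 11mer it went from 0.058 to 0.119. Leaving out the 11mer baseline library of this set, whose counts entered the estimate of spread, gave 4406, 4758 and 3962 genes. The NoPP_Streptag baseline library had 3 of 12 fibroblast collagen genes above all other HEK293 libraries (median of the 12 genes 17.8 CPM), and without it the NoPP_Streptag comparison gave 1623 genes and the 99mer comparison 2621. Leaving out the parental poly(I:C) library gave 1044, 905 and 914.

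The 2 parental libraries shared by these comparisons cannot be split, so part of any overlap between them may come from the shared controls. Streptag and NoPP_Streptag shared 378 rising and 585 falling genes, against 25.6 and 69.4 for independent lists. Streptag and 99mer shared 280 and 298 (31.2 and 34.1 for independent lists), and NoPP_Streptag and 99mer 253 and 411 (21.9 and 57.4). In 20 simulations of unchanged lines with shared controls at most 2 genes were shared in either direction, but such lines have almost no called genes, so the overlap that shared controls add to long lists is not known from them. The covariance of the fold changes was 1.44, 1.39 and 2.01 for these pairs, against means of 0.928, 0.935 and 0.928 in the simulations. Their Pearson r was 0.393, 0.405 and 0.516, against simulated means of 0.495, 0.496 and 0.493. The uORF−/− and 11mer comparisons at baseline also shared their parental libraries. They had 4 rising genes in common, against 0.0253 for independent lists. The covariance of that pair was 0.713 and its Pearson r 0.281, below the simulated means of 0.824 and 0.479.

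**Figure D5:**
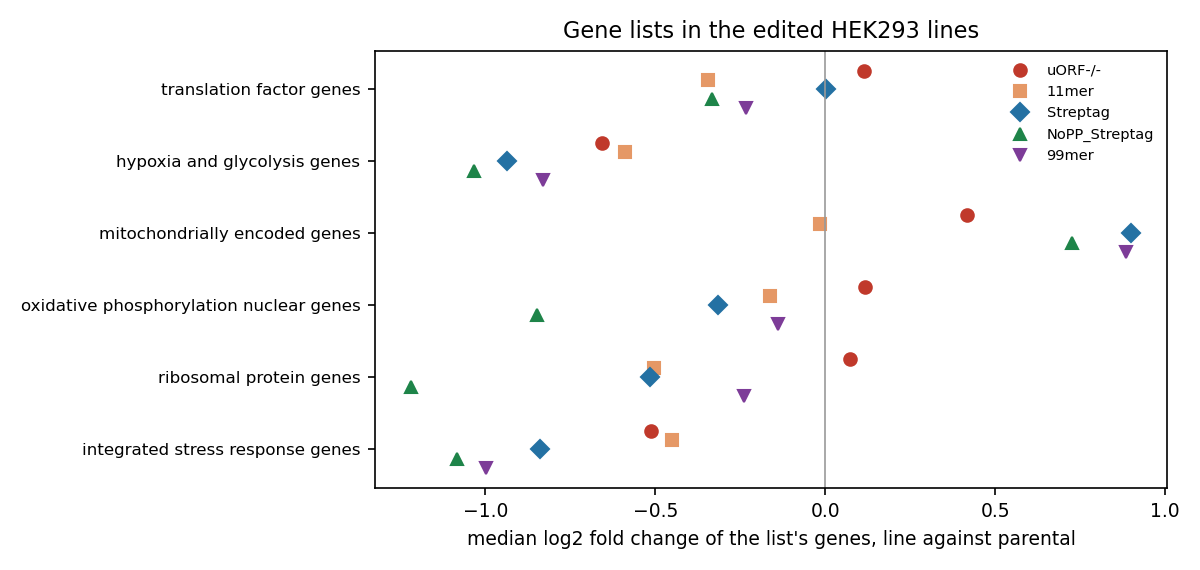
Median log2 fold change of the genes of each list, edited line against parental, for uORF−/− and 11mer at baseline and for Streptag, NoPP_Streptag and 99mer over both treatments. Integrated stress response genes had medians from −1.08 (NoPP_Streptag) to −0.45 (11mer), and with RLE scaling the median changed sign for mitochondrially encoded genes in 11mer (0.04) and translation factor genes in Streptag (−0.01). Every comparison used the parental baseline library of the first set, so a likeness between the lines is not independent evidence.

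The 3 libraries with the suffix _p, whose meaning the labels do not give, were compared with the baseline libraries of the same lines. By edgeR 0 of 19574 genes differed, with 632 at an unadjusted p under 0.05, and by DESeq2 11. Replication-dependent histone genes had the largest list median, 3.15 over 9 genes, of which 0 passed over all genes and 8 when adjusted over the list alone (adjusted p = 0.464 with an estimated correlation). All 9 were higher in the _p library of the parental line (median 48.9 against 2.84 CPM) and of 11mer (128 against 2.64 CPM), but only 3 of 9 in that of uORF−/− (2.01 against 1.80 CPM). PPP1R15A was at 0.09 ± 0.10 (adjusted p = 1.00). Leaving out the uORF−/− _p library gave 73 genes and leaving out the uORF−/− poly(I:C) library 69.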

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

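The tests on the control libraries below were chosen after the result was seen. The LPS response of RNA differed between uORF−/− and wild-type kidneys, by the test of the difference itself, for 14 genes. The difference of responses was −4.22 for Slc14a2, −2.81 for Cish, −2.49 for Slco4a1, −1.84 for Umod, 2.14 for Bcl6, 2.52 for Bc1, 2.08 for Hba-a2, 1.94 for Fabp4, 1.82 for Clec2h and 1.73 for Gadd45a (log2). In footprints it differed for 33 genes, by −4.07 for Slc14a2, −2.38 for Aqp2, 2.90 for Ucp1, 2.84 for Plin1, 2.18 for Car3 and 2.02 for Mrc1. Only the 14 RNA genes were weighed further.

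For 11 of these 14 genes the genotypes differed more in the control kidneys than after LPS, and for Slc14a2 the control difference was 2.95 against −1.25 after LPS. In 8 of the 14 genes footprints had the same control difference of at least 2-fold. For those 8 this argues against a fault of the control RNA libraries alone. The sign was the same in 13 of 14. For the genes short of 2-fold or of the other sign such a fault stays open. Bc1 was at −1.29 in RNA and 2.06 in footprints, and Umod at 1.07 and 0.52. A larger share of collecting duct in the uORF−/− control was not excluded as a source of the Slc14a2 difference. The 7 other collecting duct genes had a lower median control difference of 0.81 (SD 0.716). All 7 were higher in RNA, from 0.27 for Scnn1b to 2.35 for Aqp2, and Aqp2 came close to Slc14a2. The 7 genes stand for the collecting duct at large, so they cannot test a larger share of its inner medullary part. What stays open is that each genotype has 1 control kidney, so a trait of 1 animal or of the piece of tissue taken, such as its share of inner medulla, may give the same pattern as a difference of genotype. An effect of the genotype also stays open, as untested.

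The human tables count reads on a sequence for each edited line, in the parental line as a control. The uORF−/− sequence had 63 reads in the parental poly(I:C) library of the second set and 211 in the 11mer poly(I:C) library of the same set, and the labels give both lines another genotype. The bases of these sequences are not given, so reads of the unedited transcript on them cannot be told from reads of the edited one.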

How the results depend on the processing

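Fits without the 2 doubted HEK293 baseline libraries and with LPS footprints taken off the controls were chosen after seeing the data; the other alternatives were planned. Kidney LPS counts in RNA and footprints stayed within 1.5 times under all alternatives, at 7256 to 10064 genes and 8155 to 9547 when 1 library was left out. Ppp1r15a footprints were higher in uORF−/− kidneys in all alternatives, at 1.21 to 1.54 when 1 library was left out, and PPP1R15A rose with poly(I:C) at 1.17 to 1.38. Where leaving out a library left a group with 1 sample, that sample was assumed to vary like the other groups. On simulated counts of the same depth and number of libraries, 27.8% of 2-fold changes were found for translational efficiency between genotypes and 5.81% for uORF−/− at baseline, and how much of this limit is depth was not tested. Where not said otherwise below, the cause was not tested.

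DESeq2's Wald test gave 93 genes for the genotype difference in RNA, 76 in footprints, 45 and 202 for the differences of LPS response, 1525 for translational efficiency under LPS, 481 for poly(I:C), 487 for uORF−/− and 12 for 11mer at baseline, 3172 for Streptag and 11 for the _p libraries. With no filter on low counts these were 271 and 443 for the genotype difference, 180 and 841 for the differences of LPS response, 1275 and 29 for translational efficiency under LPS and between genotypes, 65 for 11mer, 9 and 13 for the differences of poly(I:C) response of uORF−/− and 11mer, and 103 for _p; this setting tests more genes. A minimum count of 30 gave 21 genes for the footprint difference of LPS response and 3 for 11mer. Genotype as an additive term, which includes the control kidneys, gave 1 gene in RNA and 1 in footprints.

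With the replicate block of animals, translational efficiency changed for 2328 genes under LPS and 52 between genotypes. The genotype difference of Ppp1r15a passed the threshold (1.25, adjusted p = 6.65e-10), as it did with no filter (1.24, 1.22e-06). Both of these p-values, and the 52 calls between genotypes, rest on a spread pooled over genes. The block changed no other count of calls, since it applies to no other comparison. Without the sequencing set as a term, 5 genes differed in uORF−/− and 0 in 11mer. The first HEK293 set alone gave 78 genes for poly(I:C), with DDIT3 reversed (−0.18), and the second alone 295, both with fewer libraries. Without the 2 doubted baseline libraries the counts were 538 for poly(I:C), 5442 for Streptag, 3956 for NoPP_Streptag and 4989 for 99mer. With the LPS share taken off the control footprints, translational efficiency reversed for Cxcl10 (0.26), Ifit1 (0.046), Gbp2 (0.61), Fgb (0.28) and Lcn2 (9.60), by the subtraction itself. With the share taken off and the uORF−/− control footprint library left out, Ifit1 (−0.70) and Gbp2 (−0.67) stayed negative.

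Leaving out 1 library gave 7 to 182 genes for the genotype difference in RNA, 9 to 126 in footprints, 49 to 146 and 48 to 178 for the differences of LPS response, 129 to 1122 for translational efficiency under LPS and 0 to 2 between genotypes. It gave 97 to 638 genes for poly(I:C), 96 to 755 for uORF−/−, 8 to 998 for 11mer, 0 to 202 and 2 to 213 for their differences of response, 1044 to 4406 for Streptag, 905 to 4808 for NoPP_Streptag, 910 to 3962 for 99mer and 0 to 73 for _p. Ppp1r15a ranged from −0.17 to 0.43 for the genotype difference in RNA, −0.24 to 0.38 for translational efficiency under LPS and 0.94 to 1.52 between genotypes, and its footprint difference of LPS response from −0.33 to 0.0011. In HEK293 cells PPP1R15A ranged from −0.10 to 0.69 in uORF−/− at baseline and from −0.49 to 0.87 for the difference of poly(I:C) response of 11mer, and DDIT3 from −1.91 to 0.030 in uORF−/− at baseline.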

Other observations

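The tests of the fall in translational efficiency of interferon-stimulated genes and of the leukocyte transcripts were chosen after the result was seen, and those of other splits of the samples before. Beyond the groups in the report, metabolism and vessel genes of the kidney differed after LPS. Of 30 fatty acid oxidation and peroxisome genes 16 rose and 2 fell in RNA (17 and 2 adjusted over the list alone; adjusted p = 0.700 with an estimated correlation), with Pdk4, an inhibitor of pyruvate oxidation, at 7.01 ± 0.35. Of 18 endothelial genes 4 rose, such as the adhesion gene Selp (6.74 ± 0.38), and 9 fell, such as Plvap (−2.41 ± 0.12), a component of capillary pores (0.584). Of 12 podocyte genes 5 fell and 1 rose, with the transcription factor gene Tcf21 at −3.01 ± 0.28 (0.745). Among 20 endoplasmic reticulum chaperone genes 6 rose and 5 fell, and Xbp1, a transcription factor of the unfolded protein response, rose by 2.70 ± 0.15 and Dnajb9 by 1.60 ± 0.14 (0.745). Of 30 translation factor genes 13 rose and 1 fell, led by Eif6, which keeps ribosomal subunits apart (2.18 ± 0.15; 0.478), and of 64 ribosomal protein genes 43 rose and 0 fell (49 adjusted over the list alone; 0.700). Of 7 red blood cell genes 6 rose and 1 fell, with Hba-a2 at 2.85 ± 0.39 (0.700).

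Each edited HEK293 line had reads on the sequence of its own change in all of its libraries: 46 to 312 in uORF−/−, 13 to 387 in 11mer, 48 and 127 in 99mer, 38 and 40 in Streptag and 26 and 103 in NoPP_Streptag. The uORF−/− sequence also had 13 to 211 reads in the 5 libraries of 11mer, 1 to 63 in the 5 parental libraries and 16 in 1 of 2 libraries of 99mer. In the 5 parental libraries the other 4 sequences had 4 reads at most. The bases of the sequences are not given, so overlap with the unedited transcript could not be judged.

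Translational efficiency fell after LPS for 17 of 30 interferon-stimulated genes. In genes almost silent in control RNA, the control footprint libraries held 0.769% and 0.902% of the mean raw LPS footprint count, not scaled for depth. LPS footprints carried into the control libraries are a candidate explanation of part or most of the fall. With that share taken off, the list test gave an adjusted p of 0.165 in place of 3.2e-21. The median of the 17 genes went from −1.09 to −0.47, and their median SE from 0.208 to 0.274, so the calls ended both by a smaller fall and by a wider error. These values rested on single control footprint libraries. With the share taken off and the uORF−/− control footprint library left out, Ifit2 was at −1.01, Mx2 at −1.26, Cmpk2 at −0.95 and Gbp3 at 0.25. With the wild-type control footprint library left out instead, they were at 0.93, 7.35, −0.83 and 2.48. Whether carried footprints are the whole cause in every gene stays open. With all libraries kept, 2 of the 17 still fell, Cmpk2 (−0.87 ± 0.18, adjusted p = 0.019) and Ifi44 (−0.86 ± 0.19, 0.025). With the highest share of any gene used to estimate the share, only Ifi44 did (−0.84 ± 0.19, 0.0308), and Cmpk2 was at an adjusted p of 0.0672. Leaving out each of 12 libraries from the fit with the mean share kept the call of Cmpk2 in 8 and of Ifi44 in 5 (adjusted p up to 0.190 and 0.111). Removing the genes that take most of the counts moved the 17 genes by 0.012 at most and so tested nothing, and a true fall of translational efficiency also stays open.

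The 11mer baseline library of the first HEK293 set held transcripts of leukocytes. All 24 listed neutrophil and monocyte genes were above the highest other HEK293 library, with a median of 13.6 CPM against 1.37 in the highest of the others, as were 10 of 13 lymphocyte genes, and IL1B was at 152, CSF3R at 34.5 and OSM at 32.1 CPM. RNA of leukocytes mixed into this library is a candidate explanation, and of the 24 genes 1 exceeded 1 CPM in the median HEK293 library. Of the 24 genes 10 exceeded the highest 1% of the 7851 genes that had no count in other libraries, where chance gives 0.24. This argues against a low background along the whole genome as the whole source in those 10. The 7851 genes were picked as silent elsewhere and the 24 were not, so 0.24 is not an exact expectation. Of the 7851 genes 1537 (19.6%) had a count in this library, so a background as a part of the source stays open. No biological explanation was tested, and where such RNA came from stays open.

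Other splits of the samples were counted. For poly(I:C), 100 of 256 possible swaps within the 9 pairs were fitted, the real one included. Only 1, the real one, gave as many as 188 genes, and the highest of the others gave 1. That share is under 0.05, which makes chance unlikely but does not exclude it. A swap also moves the response of its pair into the spread, so low counts in the others were partly built in. For the _p libraries, the 10 splits of 6 libraries are too few for a share under 0.05, and the real count and the highest other were both 0, so all 10 splits gave as many.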
